A study of Physcomitrium patens with 20 samples.

How the data were processed

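Polyadenylated RNA of protonema, the filamentous juvenile tissue of the moss Physcomitrium patens (cultivar Grandsen per the labels), was sequenced in 20 libraries after 7 days of growth. The libraries came from wild type and 6 mutants of DNA methyltransferase genes. Per the labels, there were 3 libraries each of wild type (wt), drm1drm2 (drm12 below), cmt, dnmt3b, met/dnmt3b and cmt/dnmt3b, and 2 of met. The labels also gave each library a batch. Batch 1 held wt replicates 1 and 2, drm12 replicates 1 and 2, cmt replicates 1 and 2, both met libraries and the 3 met/dnmt3b libraries. Batch 2 held the third replicates of wt, drm12 and cmt, and the 3 libraries each of dnmt3b and cmt/dnmt3b. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

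The authors deposited 1 table of raw counts for the 20 libraries, with 31967 gene rows and 241351 rows with numeric identifiers, which are transposable elements (TEs) according to the name of the deposited table. Per the submitters' processing notes, Trim Galore 0.6.0, cutadapt 1.15 and STAR 2.7.0f were used, with no role given for each. The counting step, the treatment of reads that map to several places, the strand setting, the genome build and the annotation are not given in the sources used here. These choices bear most on the TEs, since reads shared between near-identical copies can be dropped, split or assigned to 1 copy, so the level of a single TE row is uncertain. Counts of genes that overlap TEs or have close paralogs are uncertain for the same reason. No row lacked a gene or TE identifier, and no column outside the 20 libraries was present.

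The deposited counts summed to between 14236575 and 21811993 per library. A count of 0 in a library allows up to 3 counts of that total, and intervals on shares are 95% exact (Clopper-Pearson) binomial intervals. Both cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 7.61 and 169.6 over the 19 pairs, so none was taken for a repeat of another.

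The main fit was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the counts of all 20 libraries, with genotype and batch as terms, so that the batch effect was estimated from wt, drm12 and cmt, the genotypes present in both batches. Normalisation factors were trimmed means of M-values (TMM) over genes and TEs together. The low-count filter of edgeR, by group, with a minimum count of 10 and a minimum total of 15, left 20149 genes and 6602 TEs. Adjusted p-values are Benjamini-Hochberg values over the 26751 features, with a threshold of 0.05. The 13 comparisons were each mutant with wt, each of the 2 double mutants with each of its single mutants, the double mutants with each other, and the interaction of met with dnmt3b and of cmt with dnmt3b. An interaction here is the log2 level of the double mutant, minus those of both single mutants, plus that of wt. Levels are CPM values computed from the counts with the normalisation factors, as mean ± SD.

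Against a group at 0 counts, a fold is given as a lower bound from 3 counts over the group. Where a group had 1 to 3 counts, the ratio of CPM comes with its 95% counting interval.

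The share of counts in TEs was compared by a two-sided exact permutation test of the means with Benjamini-Hochberg adjustment over 6 tests. The two-sided p adds the smaller tail to itself, so groups of 3 against 3 cannot give a p below 0.1 there, and 2 against 3 none below 0.2. Shared calls between mutants were set beside the overlap of independent lists (the product of both counts of calls over the number tested) and beside the mean of 10 simulations in which no genotype differed. The 3 wt libraries cannot be split into parts of at least 2, so part of any excess may come from the shared wt libraries.

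Gene levels along chromosomes were summarised from genes with a mean of at least 2 CPM. The log2 of CPM plus 0.5 was taken relative to the median of the gene over the 20 libraries and then to the median of the library, and medians were taken over the genes of each chromosome and over 4 successive parts of it with like numbers of genes. The chromosome and order of a gene were read from its identifier (the number that follows the prefix, then the last number). That convention was not checked against an annotation of this build. Medians were given for 27 chromosomes with at least 200 such genes, 16800 genes in all.

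The scripts were tested on simulated data. Counts were drawn from the fitted means, dispersions and library sizes of 20149 genes and 6602 TEs, with 200 genes and 200 TEs changed per mutant. For genes changed 4-fold, between 68% (cmt/dnmt3b with wt) and 81.8% (cmt with wt) were recovered. For genes changed 2-fold, between 7.8% (dnmt3b with wt) and 20.4% (drm12 with wt) were recovered. For TEs changed 4-fold, between 2.6% (met with wt) and 6.4% (dnmt3b and cmt/dnmt3b with wt) were recovered. Of unchanged features, at most 0.0204% were called. A simulated doubling of 1 chromosome in 3 libraries, a log2 change of 1, came back as medians of 0.80 to 0.84 over 16836 genes. The test for neighbouring genes gave a ratio of 0.802 (permutation p = 0.922) for random calls and 3.10 for calls with added neighbours (permutation p = 0.0001, the smallest possible), over 15905 genes.

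Whether replicate numbers pair the libraries was checked from the correlation of deviations from the group means. Over 31 pairs of libraries with the same number, r ran from -0.51 to 0.48, and 6 pairs were over 0.1. In cmt with wt, each of the 3 pairs was over 0.1 (0.37, 0.32 and 0.48), so the numbers were taken to pair these libraries. Both libraries of each pair are also in the same batch. Batch was not removed before the correlation, so it may add to these values. In the other 10 comparisons checked, not every pair was over 0.1, so the numbers were not taken as pairs. In some of them, such as drm12 with wt, libraries with the same number also share a batch.

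The features named in the text follow a rule fixed before the data were examined. Among features past the threshold with an absolute log2 fold change of at least 1, libraries of the groups compared that do not overlap, and a mean of at least 5 CPM in the higher group, the 2 genes and 2 TEs with the largest change in each direction were selected. For comparisons between mutants and for interactions, fewer of these are named in the text. For the interactions no separation of libraries was asked, and the mean of 5 CPM was asked of the highest of the groups involved. A TE that was the only one to fall in a comparison is also named, chosen after its values were seen. Fixed gene lists (DNA methylation machinery, RNA silencing, histones, photosynthesis and others) could not be used, because 0 gene identifiers of the deposited table matched the reference table of gene names (the RefSeq assembly ASM5946719v1). So no gene has a name here, the set tests were not run, and the transcripts of the mutated methyltransferase genes could not be used to check the labels. The TEs have no class.

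Alternatives fixed before the data were examined were no batch term, the replicate number as a block, RLE size factors, DESeq2 1.42.0, TMM factors from genes alone, no low-count filter, a minimum absolute log2 fold change of 1, libraries of 1 batch alone, each replicate left out in turn, and adjustment for genes and TEs separately. Leaving out 7 chromosomes (10, 13, 16, 18, 19, 25 and 27), with TMM factors from all features or from genes alone, and leaving out the drm12 libraries were chosen after seeing the data.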

Results

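The transcriptomes of wild-type moss protonema and of 6 DNA methyltransferase mutants were compared by mRNA sequencing, to set the effect of losing CG methylation beside that of losing methylation outside CG. In this moss, MET maintains CG methylation, CMT maintains CHG methylation, DNMT3b is the main enzyme for CHH methylation of heterochromatin, and DRM1 and DRM2 are the relatives of the plant enzymes guided by small RNA. The 20 libraries held between 14236575 (wt replicate 3) and 21811993 (cmt replicate 3) counts. At least 1 count was found for 25846 of 31967 genes and for 28715 of 241351 TEs.

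TEs held a small part of the transcripts in wild type, 0.0784% ± 0.0276 of counts (SD, n = 3), and the largest part in cmt/dnmt3b. There the share was 3.20% ± 0.351 (SD, n = 3), 40.9 times that of wt. It was 0.409% ± 0.155 in cmt (n = 3), 0.374% ± 0.0715 in met/dnmt3b (n = 3), 0.235% ± 0.0383 in dnmt3b (n = 3), 0.20% ± 0.0125 in met (n = 2) and 0.146% ± 0.107 in drm12 (n = 3). Every library of met, cmt, dnmt3b, met/dnmt3b and cmt/dnmt3b lay above the highest wt library (0.109%). In drm12 only replicate 3 did, at 0.270% (95% interval 0.267 to 0.272%), against 0.0874% and 0.0809% in the other 2. By the two-sided exact permutation test the difference from wt had p = 0.1 in cmt, dnmt3b, met/dnmt3b and cmt/dnmt3b, the smallest p that 3 against 3 libraries can give (adjusted p = 0.15). By the same exact permutation test it had p = 0.2 in met, the smallest p that 2 against 3 libraries can give (adjusted p = 0.24), and p = 0.4 in drm12. The TE share also went with batch. In wt it was 0.109% in the batch 2 library against a mean of 0.0629% in batch 1, and in cmt 0.587% against 0.319%. Within batch 1 the ratio to wt was 1.34 in drm12, 3.18 in met, 5.07 in cmt and 5.94 in met/dnmt3b. Within batch 2, where wt is 1 library, it was 2.47 in drm12, 5.37 in cmt, 2.15 in dnmt3b and 29.3 in cmt/dnmt3b. Without drm12 replicate 3, the difference of drm12 from wt fell from 0.0676 to 0.00574 percentage points.

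**Figure D1:**
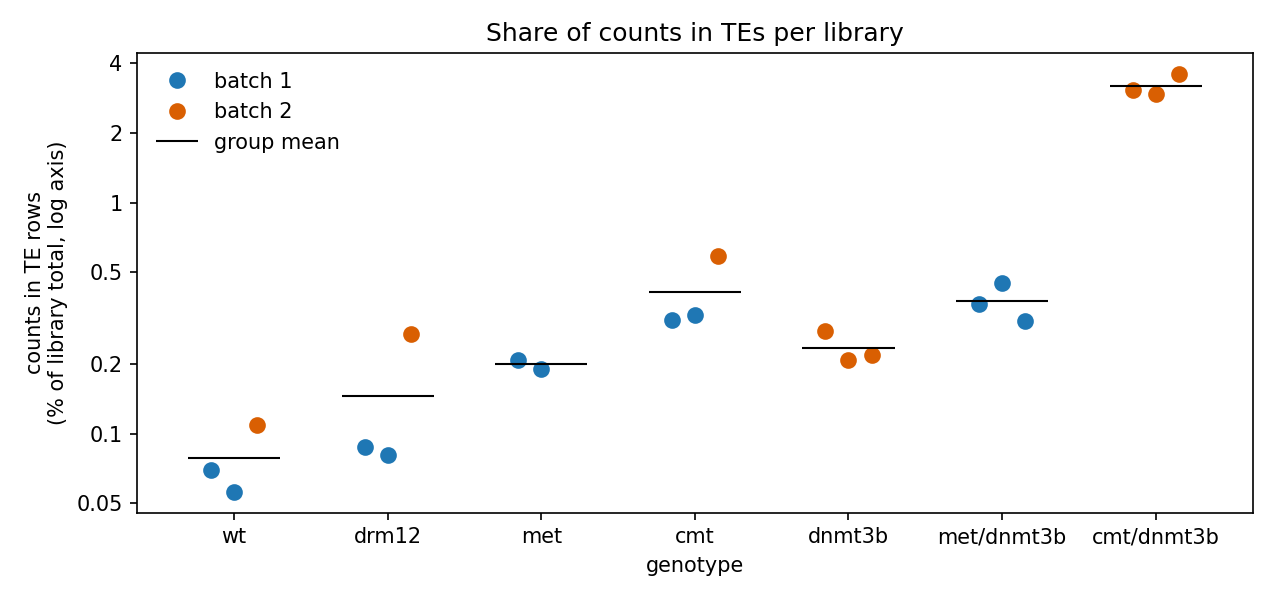
Counts in TE rows as a percentage of the library total (log axis) for each of the 20 libraries by genotype, coloured by batch, with the group mean as a line. The 3 cmt/dnmt3b libraries lie between 2.94% and 3.60%, and the other libraries lie at or below 0.587%.

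In cmt/dnmt3b between 14471 and 15658 TEs had at least 1 count, against 1324 to 3216 in wt, 1735 to 5050 in drm12, 2338 and 4961 in met and 4059 to 8706 in cmt, and the 10 TEs with the most counts held 8.10 to 12.9% of TE counts, against 23.1 to 37.3% in wt. In met/dnmt3b between 8490 and 9967 TEs were detected, and in dnmt3b between 5309 and 6399, with 12.3 to 13.1% and 12.1 to 13.7% of TE counts in the top 10. The top 10 held 26.5 to 42.8% in cmt and 30.9 and 45.8% in met, within or above the range of wt.

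With DRM1 and DRM2 lost, few transcripts passed the threshold, which does not show that few changed. In simulations of drm12 with wt, 20.4% of genes changed 2-fold and 5.8% of TEs changed 4-fold were recovered. The simulated TEs started from a level averaged over the genotypes, so their rate does not cover rises from a very low wt level. The gene Pp3c24_1550 rose 3.0-fold, from 46.2 ± 15.9 CPM in wt to 140 ± 23.0 in drm12 (SD, n = 3 each; log2 fold change 1.64 ± 0.22 SE, edgeR adjusted p = 0.0037). Pp3c6_3920 fell from 5.35 ± 3.77 to 0.320 ± 0.115 CPM and Pp3c2_22630 from 426 ± 126 to 134 ± 22.8 CPM (n = 3 each). Among TEs, 851079 went from 0.142 ± 0.191 CPM in wt to 25.6 ± 11.9 in drm12 (log2 fold change 7.35 ± 0.51, adjusted p = 4.52e-07), and 754623 from 0.162 ± 0.0998 to 5.32 ± 4.79. TE 929067 fell from 8.68 ± 3.23 to 1.54 ± 0.768 CPM. By edgeR's quasi-likelihood test, 1 gene rose and 2 fell, and 6 TEs rose and 1 fell. DESeq2 gave 22 genes and 12 TEs, and with no low-count filter 79 genes rose and 30 fell. Within batch 2, where each group is 1 library whose spread is borrowed from the other genotypes, 1763 genes (904 up, 859 down) and 105 TEs differed, and without drm12 replicate 3 the count of genes was 18; 1 gene differed without wt replicate 3 or without drm12 replicate 2. The TE count was 2 without any 1 of the wt libraries and 4 without drm12 replicate 2.

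Loss of MET raised TEs and some genes with few or no counts in wild type. Pp3c24_2580 had 0 counts in wt and 5.95 ± 4.23 CPM in met (n = 2), at least 81.7-fold higher (adjusted p = 0.000248), and Pp3c16_18789 was at least 94.4-fold higher (6.71 ± 1.37 CPM against 0). Pp3c26_640 fell from 11.9 ± 16.1 to 0.0527 ± 0.0746 CPM (ratio wt to met 209.6, 95% counting interval 58.0 to 1731), and Pp3c21_7640 from 11.1 ± 9.59 to 0.320 ± 0.368 CPM. TE 869223 went from 0 counts in wt to 14 ± 1.27 CPM, at least 199.2-fold higher. TE 781592 went from 0.0224 ± 0.0389 to 65.5 ± 17.0 CPM (adjusted p = 4.54e-06, ratio 2824, 95% counting interval 506.8 to 111530). In all, 50 genes rose and 59 fell, while 105 TEs rose and 1 (886884, adjusted p = 0.0471) fell (edgeR's quasi-likelihood test). Of the genes that rose, 22 (44%) had a wt mean under 0.5 CPM. The count of genes moved with most choices. It was 1081 within batch 1, 26 with no batch term, 2181 without the drm12 libraries and 600 by DESeq2. It was 69, 13 and 196 without wt replicates 1, 2 and 3 in turn and 30 without met replicate 1, and the TE count was 54, 35, 53 and 268 without wt replicate 1, wt replicate 2, met replicate 1 and met replicate 2. The balance of the gene calls turned without wt replicate 2 (9 rose, 4 fell), met replicate 1 (18 and 12) or met replicate 2 (57 and 31), with no batch term (21 and 5) and with the replicate number as a block (26 and 24). The TE count was 61 with no batch term and with the block, 189 by DESeq2, 259 without the drm12 libraries and 183 with genes and TEs adjusted separately; with no low-count filter there were 1114 genes and 446 TEs.

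Loss of CMT raised TEs and genes together. Pp3c11_13750 had 0 counts in wt and 55.4 ± 29.5 CPM in cmt (n = 3 each), at least 730.1-fold higher (adjusted p = 3.97e-07), and Pp3c9_22420 was at least 224.2-fold higher (15.9 ± 0.859 CPM against 0). Pp3c24_13310 fell from 13.9 ± 18.5 to 0.0404 ± 0.0350 CPM and Pp3c9_2960 from 5.27 ± 3.14 to 0.0614 ± 0.106. TE 974228 went from 0.0241 ± 0.0418 CPM in wt to 248 ± 26.3 in cmt (adjusted p = 5.94e-10, ratio 10593, 95% counting interval 1901 to 418420), and TE 816641 from 0 counts to 21.6 ± 9.30 CPM, at least 325.0-fold higher. Few TEs fell: 936921 went from 23.9 ± 7.17 to 0.907 ± 0.298 CPM (adjusted p = 3.07e-08) and 928527 from 33.4 ± 6.03 to 13.8 ± 2.40. In all, 623 genes rose and 419 fell, and 694 TEs rose and 9 fell (edgeR's quasi-likelihood test). That fit did not use the pairing of cmt and wt libraries taken from their numbers. With the replicate number as a block, 490 genes rose and 322 fell, and 486 TEs rose and 9 fell. Of the genes that rose, 227 (36.4%) had a wt mean under 0.5 CPM, and of the TEs that rose, 495 had 0 counts in the wt libraries. Within batch 1 there were 238 TEs of 1321 that passed its filter, and within batch 2, with 1 library per group, 621 genes and 378 of 7792 TEs. With no batch term there were 393 TEs, without the drm12 libraries 1667 genes, and with no low-count filter 1734 genes and 1059 TEs. The TE count was 285 without wt replicate 3, and the gene count was 636, 596 and 661 without wt replicate 2, cmt replicate 1 and cmt replicate 2.

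With DNMT3b lost alone, more genes than single TEs passed the threshold, but in simulations changes of single TEs were found less often. Simulated 4-fold changes in dnmt3b, rises and falls together, were recovered for 71.6% of genes and 6.4% of TEs. The simulated TE levels were averaged over the genotypes, so this rate does not cover rises from a very low wt level. Of the TEs tested, 76.1% had a positive log2 fold change. The median log2 fold change was 1.17 for TEs and 0.036 for genes. Pp3c17_12750 went from 0.0241 ± 0.0418 CPM in wt to 5.25 ± 1.40 in dnmt3b (n = 3 each; adjusted p = 0.00377, ratio 221.5, 95% counting interval 39.7 to 8748) and Pp3c13_11610 from 0.139 ± 0.121 to 11.7 ± 1.23. Pp3c16_23620 fell from 44.8 ± 26.4 to 0.279 ± 0.216 CPM (adjusted p = 0.0114) and Pp3c4_2660 from 56.8 ± 32.0 to 0.943 ± 0.222. TE 979511 went from 0.160 ± 0.169 to 5.99 ± 4.44 CPM and TE 805494 from 0.0224 ± 0.0389 to 7.50 ± 2.98 (adjusted p = 0.000556 for each). In all, 95 genes rose and 182 fell, and 32 TEs rose and 1 (788449, adjusted p = 0.0406) fell (edgeR's quasi-likelihood test). Genes of chromosome 19, whose level was raised in wt replicate 3 (below), made up 33 of the 182 falls (18.1%) and 3.0% of the genes tested. The dnmt3b libraries are all in batch 2, where wt has 1 library. With no batch term 1711 genes and 270 TEs differed, with DESeq2 1135 and 71, within batch 2 539 and 53, and without the drm12 libraries 474 and 57. The replicate number as a block left 25 genes, 14 up and 11 down, and 6 TEs, and with no low-count filter there were 1698 genes. Leaving out 1 library gave as few as 44 genes (22 rose, 22 fell) and 9 TEs (without dnmt3b replicate 1), 60 and 14 without dnmt3b replicate 3, 152 and 21 without dnmt3b replicate 2, 136 and 21 without wt replicate 2, 175 genes without wt replicate 1 and 15 TEs without wt replicate 3.

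The double mutant of MET and DNMT3b raised 52.9% of the TEs tested. The low-count filter admits TEs for their level in a double mutant alone, and with no filter 3929 of 28715 TEs rose. Pp3c24_2580, at 0 counts in wt, reached 43.2 ± 2.42 CPM in met/dnmt3b (n = 3 each), at least 609.0-fold higher (adjusted p = 1.31e-06), and Pp3c27_8510 was at least 125.2-fold higher (8.89 ± 1.25 CPM against 0). Pp3c18_18430 fell from 37.3 ± 20.7 to 2.13 ± 0.273 CPM and Pp3c8_1520 from 150 ± 145 to 11.8 ± 1.3. TE 869223 was at least 125.8-fold above wt (8.91 ± 2.83 CPM against 0), and TE 948060 went from 0.0483 ± 0.0836 to 7.73 ± 0.752 CPM (adjusted p = 4.17e-07). TEs 809690 and 879436 fell, from 20.9 ± 7.28 to 7.49 ± 1.79 CPM and from 12.7 ± 3.01 to 5.94 ± 1.43. In all, 1096 genes rose and 855 fell, and 3495 TEs rose and 9 fell (edgeR's quasi-likelihood test). Of the genes that rose, 452 (41.2%) had a wt mean under 0.5 CPM, and of the TEs that rose, 1720 had 0 counts in wt. The met/dnmt3b libraries are all in batch 1, and within batch 1 the TE count was 809 of 1321 that passed the filter there; with no batch term it was 1151, with 1212 genes. Without the drm12 libraries 4524 genes differed (2109 rose, 2415 fell), and without met/dnmt3b replicate 2 the balance also turned (776 and 1045), as it did with no low-count filter (1306 and 1624). With genes and TEs adjusted separately there were 1011 genes. Without wt replicate 3 there were 1277 genes and 1980 TEs, and without wt replicate 1, met/dnmt3b replicate 1 and met/dnmt3b replicate 3 the gene count was 987, 1043 and 1233.

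The double mutant of CMT and DNMT3b gave the most calls against wild type with all libraries, but not without wt replicate 3. Pp3c11_13750 went from 0 counts in wt to 46.3 ± 7.09 CPM in cmt/dnmt3b (n = 3 each), at least 653.0-fold higher (adjusted p = 5.54e-07), and Pp3c13_5590 was at least 115.8-fold higher (7.98 ± 1.60 CPM against 0). Pp3c9_740 fell from 16.6 ± 7.48 CPM to 0 counts, at least 365.7-fold lower (adjusted p = 9e-05), and Pp3c13_19580 from 23.9 ± 10.3 to 0.0403 ± 0.0698 CPM. TEs 976498 and 879493, at 0 counts in wt, were at least 208.0-fold and 752.5-fold higher (14.7 ± 0.786 and 53.0 ± 13.1 CPM). In all, 5267 TEs rose and 18 fell, and 1831 genes rose and 2875 fell (edgeR's quasi-likelihood test). Of the TEs that rose, 3739 had 0 counts in wt, and of the genes that rose, 732 (40%) had a wt mean under 0.5 CPM. The direction of the gene calls rested on the scaling. With TMM over genes and TEs the median gene had a log2 fold change of -0.21, and 38.9% of gene calls were rises. With factors from genes alone the median was -0.01, and 2275 genes rose and 1617 fell, 58.5% rises; with RLE factors 2256 rose and 1643 fell. Relative to the median gene, falls smaller than this shift are therefore not falls. Genes of chromosomes 16 and 10, raised as a whole in these libraries, made up 301 and 178 of the rises. Without wt replicate 3, the only wt library in batch 2, the calls were 1676 genes and 803 TEs, 2479 features against 3257 in met/dnmt3b. Without cmt/dnmt3b replicate 1 or 3 the balance of the gene calls turned (1625 rose and 1541 fell; 1532 and 1452), and with DESeq2 2310 rose and 1887 fell. Requiring an absolute log2 fold change of at least 1 left 3002 genes, 1538 up and 1464 down.

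**Figure D2:**
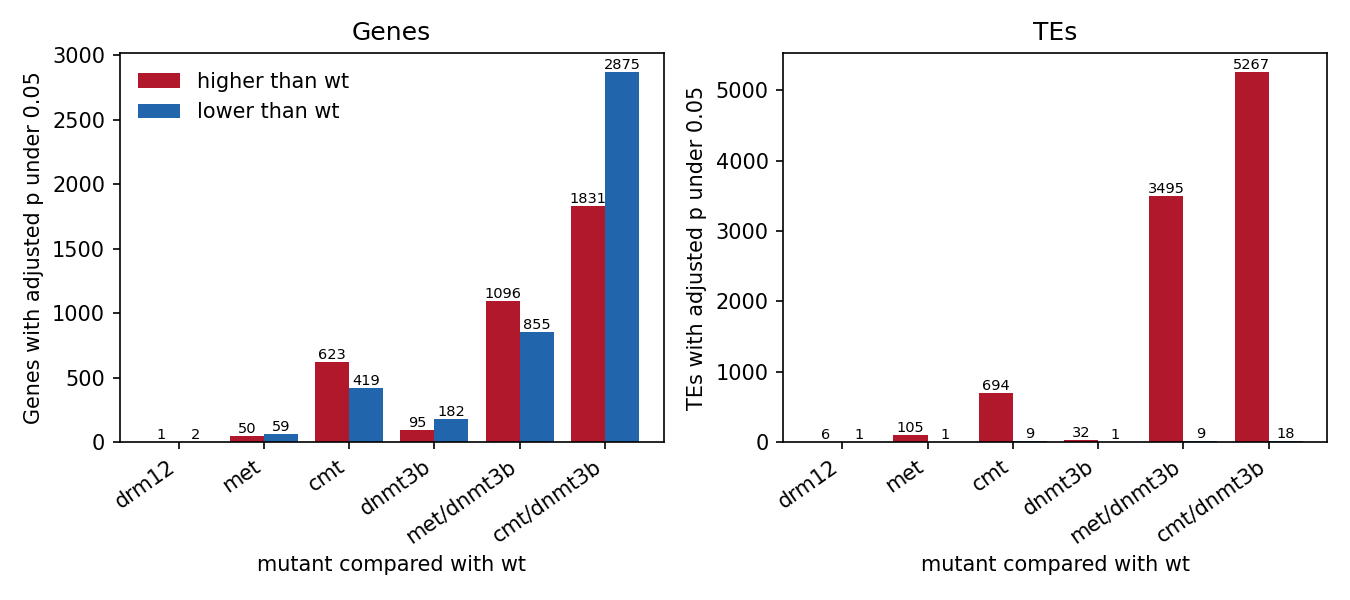
Genes (left) and TEs (right) that differed from wt in each mutant at an adjusted p under 0.05 (edgeR), as bars of counts for those higher and lower than wt. TEs that rose number 6 in drm12 and 5267 in cmt/dnmt3b, and at most 18 TEs fell in any mutant; with TMM factors from genes alone, the cmt/dnmt3b gene bars would be 2275 higher and 1617 lower.

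Transcript levels of whole chromosomes differed between libraries. In the 3 cmt/dnmt3b libraries the genes of chromosome 16 had a median log2 level 0.84 ± 0.03 (SD, n = 3 libraries, 692 genes) above their median over the libraries, a factor of 1.79, and in the other 17 libraries this median lay between -0.09 and -0.02. Chromosome 10 was raised by 0.55 ± 0.07 in the same libraries (637 genes), against -0.08 to -0.02 in the others. In wt replicate 3, chromosome 19 was raised by 0.91 (508 genes), against -0.10 to 0.07 in the other 19 libraries. Over 4 successive parts of chromosome 16 with like numbers of genes the medians ran from 0.76 to 0.90 in the cmt/dnmt3b libraries, and over those of chromosome 19 from 0.89 to 0.97 in wt replicate 3. Chromosomes 13, 18, 25 and 27 were highest in cmt/dnmt3b replicate 2 (0.18, 0.16, 0.22 and 0.22) and between -0.01 and 0.10 in its replicates 1 and 3. Apart from these 6 chromosomes in cmt/dnmt3b and chromosome 19 in wt replicate 3, the medians of the other 521 pairs of library and chromosome lay between -0.14 and 0.09. Chromosome 16 held 4.10% of the tested genes and 301 (16.5%) of the 1825 genes with a chromosome number that rose in cmt/dnmt3b, chromosome 10 held 178 (9.75%) of them, and chromosome 19 held 274 (9.55%) of 2870 falls. In cmt/dnmt3b against cmt, chromosome 16 held 253 (23.8%) of 1062 rises, and against met/dnmt3b 115 (26.1%) of 441. Chromosome 19, with 3.0% of the tested genes, held 99 (5.97%) of 1658 and 46 (6.44%) of 714 falls in these comparisons. In cmt/dnmt3b against dnmt3b it held 127 (2.89%) of 4391. Wt replicate 3 is not compared there, but is among the libraries that set the batch term. Against wt, chromosome 19 held 31 (7.42%) of 418 falls in cmt, 6 (10.2%) of 59 in met and 38 (4.45%) of 853 in met/dnmt3b. Under factors from genes alone, chromosome 16 held 398 (17.6%) and chromosome 10 265 (11.7%) of 2267 rises in cmt/dnmt3b against wt, and chromosome 19 held 191 (11.8%) of 1616 falls; chromosome 16 held 379 (25.1%) of 1507 rises against cmt and 189 (29.2%) of 647 against met/dnmt3b. With the genes of the 7 chromosomes left out, 1130 genes rose and 2399 fell in cmt/dnmt3b, 850 rose and 673 fell in met/dnmt3b, 501 and 326 in cmt, 77 and 112 in dnmt3b, and 36 and 46 in met. Under factors from genes alone these were 1342 and 1306 in cmt/dnmt3b, 877 and 649 in met/dnmt3b, 501 and 332 in cmt, 71 and 131 in dnmt3b, and 35 and 57 in met.

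**Figure D3:**
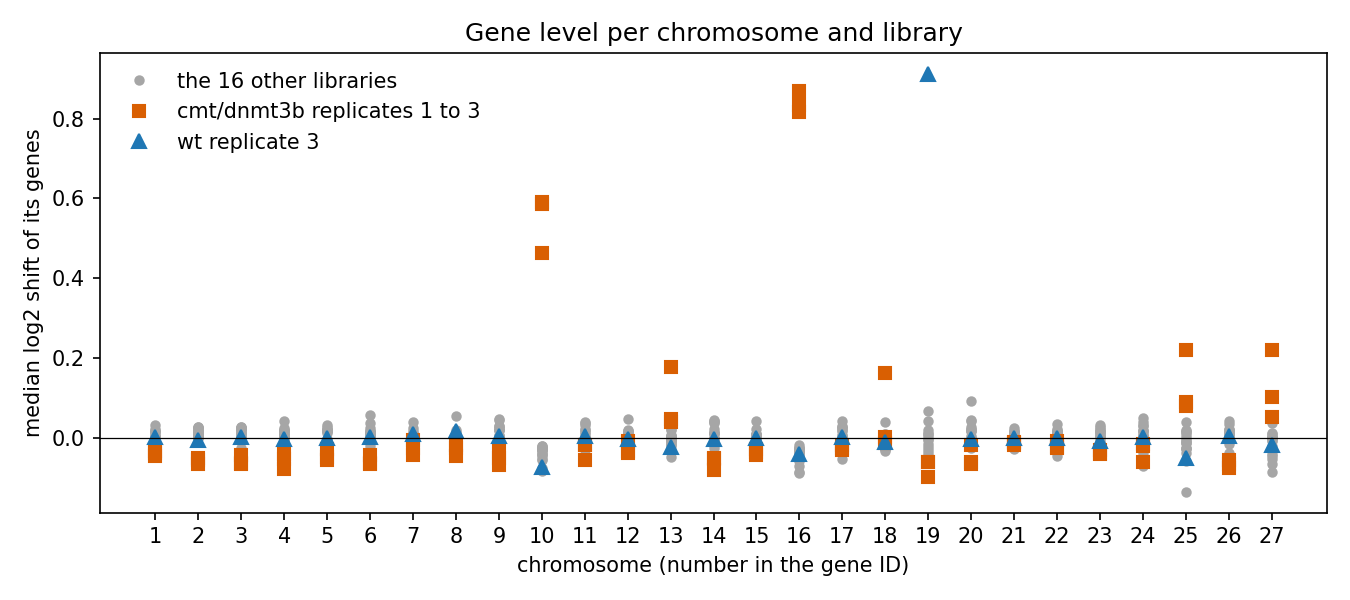
Median log2 shift of the genes of each chromosome (vertical axis) for the 27 chromosomes (horizontal axis), 1 symbol per library, relative to the median of each gene over the 20 libraries and to the median of the library. The cmt/dnmt3b libraries stand apart on chromosomes 16 (0.82 to 0.87) and 10 (0.46 to 0.59), and wt replicate 3 on chromosome 19 (0.91).

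Each double mutant was compared with its single mutants to see what the second loss adds. Adding dnmt3b to met raised TE 859228 from 0.180 ± 0.255 CPM in met (n = 2) to 5.28 ± 0.793 in met/dnmt3b (n = 3; adjusted p = 0.000439) and gene Pp3c9_24660 from 0 counts to 5.82 ± 1.64 CPM, at least 71.1-fold. TE 781592, raised in met, was lower in the double mutant (12.5 ± 9.44 against 65.5 ± 17.0 CPM, adjusted p = 0.00783), and gene Pp3c16_19750 fell from 10.7 ± 2.20 to 1.33 ± 0.395 CPM. In met/dnmt3b against met, 562 genes rose and 660 fell, and 1042 TEs rose and 10 fell (edgeR's quasi-likelihood test). The balance of the gene calls turned with RLE factors (616 rose, 521 fell), factors from genes alone (593 and 564), DESeq2 (1003 and 874) batch 1 alone (739 and 431), no batch term (303 and 300), the replicate number as a block (334 and 310), an absolute log2 fold change of at least 1 (495 and 467) and genes and TEs adjusted separately (426 and 420). It also turned without met replicate 2 (62 and 7), met/dnmt3b replicate 1 (279 and 80) or met/dnmt3b replicate 3 (355 and 155), where the TE count was 79, 514 and 676. With no batch term 306 TEs differed, with the block 562, within batch 1 397 of 1321 and with separate adjustment 1665. Without the drm12 libraries 4392 features differed, and with no low-count filter 3978.

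Adding met to dnmt3b raised Pp3c24_2580 from 0 counts to 43.2 ± 2.42 CPM (n = 3 each), at least 747.9-fold, and TE 851079 from 0.256 ± 0.159 to 45.2 ± 7.18 CPM (adjusted p = 1.05e-06). Pp3c26_1140 fell from 23.6 ± 8.12 to 1.91 ± 0.456 CPM and TE 976828 from 6.88 ± 1.46 to 0.206 ± 0.0547. In all, 470 genes rose and 272 fell, and 1567 TEs rose and 13 fell (edgeR's quasi-likelihood test). These genotypes are in different batches, so the comparison rests on the batch term. With no batch term 1334 genes rose and 1279 fell, and 471 TEs differed, and 788 of the 2322 features were called in both. Without met/dnmt3b replicates 1, 2 or 3 there were 383 genes, 987 TEs and 466 genes in turn. With genes and TEs adjusted separately there were 297 genes and 2555 TEs, and without the drm12 libraries 483 genes rose and 563 fell, with 952 TEs. The replicate number as a block left 167 genes and 521 TEs, and DESeq2 gave 1164 genes.

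Adding dnmt3b to cmt raised TE 961800 from 0 counts to 42.2 ± 2.33 CPM (n = 3 each), at least 787.2-fold (adjusted p = 0.000271), and gene Pp3c13_8950 from 0.143 ± 0.0900 to 57.4 ± 5.33 CPM (adjusted p = 6.46e-07). TE 898873 fell from 11.1 ± 6.41 to 4.06 ± 0.351 CPM and Pp3c18_18430 from 77.8 ± 56.8 to 1.08 ± 0.516. In all, 1062 genes rose and 1660 fell, and 3693 TEs rose and 26 fell (edgeR's quasi-likelihood test). With factors from genes alone 1508 genes rose and 818 fell, so 64.8% instead of 39.0% of gene calls were rises; with RLE factors it was 1504 and 815. Without cmt replicate 3, the cmt library in batch 2, 151 TEs rose and 67 fell, and 808 genes rose and 1920 fell. The balance of the gene calls turned without cmt replicate 1 (911 rose, 813 fell), without cmt/dnmt3b replicates 1, 2 or 3 (870 and 618, 920 and 812, 804 and 565), within batch 2 (1062 and 981) and with DESeq2 (1543 and 1097). The replicate number as a block left 1270 genes and 1990 TEs, and separate adjustment 1594 genes.

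Dnmt3b and cmt/dnmt3b are both in batch 2. Adding cmt to dnmt3b raised TEs and changed genes in both directions. TE 816169 went from 0 counts to 57.4 ± 4.72 CPM (n = 3 each), at least 990.9-fold higher, and gene Pp3c1_9380 from 0 counts to 8.81 ± 0.721, at least 152.4-fold. Pp3c22_5030 fell from 18.7 ± 10.8 to 0.0855 ± 0.0846 CPM (adjusted p = 6.13e-07) and TE 821870 from 21.1 ± 3.77 to 1.43 ± 0.386. In all, 5302 TEs rose and 32 fell, and 2375 genes rose and 4399 fell (edgeR's quasi-likelihood test). With factors from genes alone 3175 genes rose and 2562 fell, 55.3% rises instead of 35.1%; with RLE factors 3196 rose and 2511 fell, and with DESeq2 3230 and 2807. An absolute log2 fold change of at least 1 left 3800 genes. Leaving out any 1 library of these groups left between 8769 and 11135 of 12108 calls, counted in each fit; without cmt/dnmt3b replicates 1 or 3 the gene count was 4489 or 4161.

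The double mutants were set against each other to compare the loss of CG methylation with the loss of methylation outside CG, each on top of the loss of DNMT3b. TE 869596 was at 0 counts in met/dnmt3b and 11.2 ± 1.10 CPM in cmt/dnmt3b (n = 3 each), at least 178.6-fold higher, and gene Pp3c14_740 was at least 91.9-fold higher (5.68 ± 0.606 CPM against 0). Pp3c3_19630 was at 9.99 ± 3.59 CPM in met/dnmt3b and 0 counts in cmt/dnmt3b, at least 209.2-fold lower (edgeR adjusted p = 0.000291). TE 959199 was at 7.42 ± 3.86 against 2.43 ± 0.643 CPM. By CPM it was 3.27-fold lower, but its log2 fold change in the fit with the batch term was -5.82. Cmt/dnmt3b was higher for 439 TEs and lower for 160, and higher for 442 genes and lower for 714 (edgeR's quasi-likelihood test). The 160 lower TEs became 66 with no batch term and 68 without the drm12 libraries. Without cmt/dnmt3b replicates 1, 2 and 3 in turn they were 39, 52 and 42, and without met/dnmt3b replicate 2 51. They were 182 with DESeq2, 218 with separate adjustment and 292 with no low-count filter. In the main fit 1987 TEs had a batch 2 effect, 1965 of them higher in batch 2. With factors from genes alone it was higher for 648 genes and lower for 414, 61.0% instead of 38.2%. With the genes of the 7 chromosomes also left out, it was higher for 292 genes and lower for 340. The genotypes are in different batches: with no batch term 9707 features differed instead of 1755, and without the drm12 libraries 3793, with DESeq2 2650. Without met/dnmt3b replicates 1 or 3 the count was 919 or 1069, and without cmt/dnmt3b replicates 1, 2 or 3 it was 945, 1049 or 889. The balance of the gene calls turned without met/dnmt3b replicate 2 (511 higher, 438 lower) and without cmt/dnmt3b replicates 1, 2 or 3 (348 and 222, 360 and 296, 326 and 201), with RLE factors (617 and 412) and with DESeq2 (1028 and 826). The replicate number as a block left 336 genes and 208 TEs.

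The interactions ask whether a double mutant differs from the sum of its single mutants on the log2 scale. For met with dnmt3b, TE 805494 reached 5.47 ± 0.0974 CPM in met (n = 2), 7.50 ± 2.98 in dnmt3b and 7.81 ± 1.65 in met/dnmt3b, from 0.0224 ± 0.0389 in wt (n = 3 each), so the double mutant lay below the sum (adjusted p = 0.00199). Genes Pp3c16_20540 and Pp3c9_24660 lay above it (adjusted p = 0.00199 and 0.00314 by the same test), with 0 counts of both in met. In all, 453 genes and 21 TEs lay above the sum, and 335 genes and 11 TEs below (edgeR's quasi-likelihood test). With RLE factors 518 genes lay above and 246 below, 67.8% instead of 57.5% above. With genes and TEs adjusted separately, 1 TE differed from the sum, below it, so the TE calls depend on the adjustment. Without met replicate 2 there were 4 TEs, 11 without met/dnmt3b replicate 1 or 3 and 20 without dnmt3b replicate 2. With no batch term 7 TEs lay above and 14 below, and with the replicate number as a block 69 genes and 4 TEs differed. The 820 features became 125 without met replicate 2, 308, 361, 435, 455 and 527 without met/dnmt3b replicates 1 and 3, dnmt3b replicates 1 and 3 and wt replicate 2, 1797 with no batch term, 1329 without the drm12 libraries and 2003 with DESeq2.

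For cmt with dnmt3b, TE 903188 was at 0.0724 ± 0.125 CPM in wt, 0.0431 ± 0.0746 in cmt, 0 counts in dnmt3b and 15.1 ± 0.886 CPM in cmt/dnmt3b (n = 3 each; adjusted p = 0.00537), above the sum. Gene Pp3c9_740 was at 16.6 ± 7.48, 5.03 ± 4.0 and 4.61 ± 2.34 CPM in wt, cmt and dnmt3b and at 0 counts in the double mutant, below the sum (adjusted p = 0.0274). In all, 118 TEs and 495 genes lay above the sum, and 22 TEs and 896 genes below (edgeR's quasi-likelihood test). With factors from genes alone 713 genes lay above and 462 below, 60.7% instead of 35.6%. With the genes of the 7 chromosomes also left out, 363 lay above and 425 below, so the majority above rested on those chromosomes. Without cmt replicate 3, 57 TEs lay above and 118 below. With genes and TEs adjusted separately 29 TEs lay above and 1 below, and with DESeq2 776 TEs were called. The balance of the genes turned without cmt replicate 1 (314 above, 270 below), without cmt/dnmt3b replicates 1, 2 or 3 (312 and 234, 438 and 382, 281 and 213), within batch 2 (321 and 222), with RLE factors (729 and 447) and with DESeq2 (1321 and 977). There were 90 TEs without wt replicate 1, 71 without wt replicate 3 and 78 with the replicate number as a block. The 1531 features became 3476 without the drm12 libraries, 3074 with DESeq2, 1017 with no batch term and 614 within batch 2. Without wt replicate 2, cmt replicate 1, dnmt3b replicate 1 or cmt/dnmt3b replicates 1, 2 or 3 there were 684, 666, 950, 605, 901 and 550.

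Calls of the single mutants recurred in the double mutants. Of 694 TEs that rose in cmt, 676 rose in cmt/dnmt3b, against 553.7 for independent lists, and of 105 in met, 104 rose in met/dnmt3b, against 55.6. Of these 105, 76 rose in cmt/dnmt3b, against 83.8. Each of the 6 TEs that rose in drm12 also rose in met, in met/dnmt3b and in cmt/dnmt3b. Between the double mutants 2790 raised TEs were shared, and independent lists of these lengths would share 2788 among the 6602 tested. The low-count filter lets in TEs for their level in a double mutant alone, and 28715 TEs had a count, so for TEs the numbers for independent lists depend on that choice and no excess or lack is read from them. Of 623 genes that rose in cmt, 423 rose in cmt/dnmt3b, against 56.6 for independent lists, and of 1096 that rose in met/dnmt3b, 556 rose in cmt/dnmt3b, against 99.6. Of 419 genes that fell in cmt, 268 fell in cmt/dnmt3b, against 59.8, and of 855 that fell in met/dnmt3b, 405 did, against 122. In simulated libraries with no difference the mean overlap was 0 for each of these pairs, since the simulations called at most 2 features in a comparison. Part of the excess over independent lists may come from the shared wt libraries, which could not be split.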

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

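The tests of other splits of the libraries were chosen after the results were seen, except that of the interaction of cmt with dnmt3b.

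For met with dnmt3b, the test of the interaction itself found 820 features whose level in the double mutant differed from the sum of the single mutants, and for cmt with dnmt3b it found 1531. Both were noted because the effect of losing DNMT3b differed between backgrounds by that test. For cmt with dnmt3b, the libraries of the 4 genotypes were also reassigned at random: 3 of 60 draws, the real one included, gave at least 1531 features. That share is 0.05. The condition against chance written beforehand was a share of at most 0.05, which is met exactly. A share under 0.05 is required here, so chance cannot be excluded for that count. Most draws mixed genotypes within groups, which adds spread, so few calls were to be expected in them. The share therefore does not test the interaction apart from other differences between the genotypes. The highest other draw gave 6081, several times the real count, which points to a structure among the libraries, whose nature was not tested. The remaining draw, with 2609, kept the cmt/dnmt3b libraries together in the place of dnmt3b. With met at 2 libraries, this was not run for met with dnmt3b.

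For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Each of the other splits puts libraries of both genotypes in each group, so a true difference becomes spread within the groups. Few or no calls are then to be expected, and a 0 there adds no support to the real count. In met/dnmt3b with dnmt3b and cmt/dnmt3b with met/dnmt3b, the real split also separates the batches. In drm12 with wt, 2 of the 10 splits gave at least the 10 features of the real one, and the highest other gave 134 (drm12 replicates 1 and 3 with wt replicate 2). In cmt with wt the real split gave 1745 features, and the highest other gave 113. These fits did not use the pairing taken from the replicate numbers, and with the number as a block the real groups gave 1307. In each of 7 other comparisons 1 of the 10 splits, the real one, gave as many, and the highest of the other splits gave 0 features by edgeR, the tool used for these splits. The real values were 310 in dnmt3b, 5455 in met/dnmt3b and 9991 in cmt/dnmt3b with wt, 2322 in met/dnmt3b with dnmt3b, 6441 in cmt/dnmt3b with cmt, 12108 in cmt/dnmt3b with dnmt3b, and 1755 in cmt/dnmt3b with met/dnmt3b.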

How the results depend on the processing

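Leaving out 7 chromosomes, with either scaling, and leaving out the drm12 libraries were chosen after the results were seen. Over 25 results, 252 of 382 values under other settings stayed within the bounds set (1.5 times for counts), and 130 moved. Of 1460 values of 94 pairs of a named feature and a comparison, 1277 stayed past the threshold, 183 did not and 0 reversed (edgeR, and DESeq2 as 1 setting). These features were picked for the largest changes in the same libraries. Reversals were therefore hardly possible, and their absence adds no support. For all values below the cause was not tested, beyond the smaller number of libraries, or of TEs that pass the filter, in a batch or after leaving some out. Simulated 4-fold changes of TEs, from levels averaged over the genotypes, were recovered in 2.6 to 6.4%, and depth was not varied. The gene list tests, with estimated correlation or by fry, were not run, because no gene identifier could be matched to a name. Counts below are genes, then TEs, for comparisons with wt, and both together for the others.

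With no batch term, the TE count was 3 in drm12, the counts were 26 and 61 in met, the TE count was 393 in cmt, and the counts were 1711 and 270 in dnmt3b and 1212 and 1151 in met/dnmt3b. Met/dnmt3b gave 909 features against met and cmt/dnmt3b 9707 against met/dnmt3b, and the interactions gave 1797 (met with dnmt3b) and 1017 (cmt with dnmt3b).

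With the replicate block, cmt with wt, where the numbers were taken to pair the libraries, gave 812 genes and 495 TEs. Elsewhere the numbers were not taken as pairs. Each library correlated best with its own number in cmt with wt and, of comparisons with at least 3 pairs, in no other. The block gave 50 and 61 in met, 25 and 6 in dnmt3b, 1206 in met/dnmt3b with met, 688 with dnmt3b, 3260 in cmt/dnmt3b with cmt, 544 with met/dnmt3b and 73 in the interaction of met with dnmt3b; no other count moved by over 1.5 times.

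DESeq2 gave 22 and 12 in drm12, 600 and 189 in met, 1135 and 71 in dnmt3b, 2650 in cmt/dnmt3b with met/dnmt3b, and 2003 and 3074 in the interactions. With no low-count filter there were 109 and 22 in drm12, 1114 and 446 in met, 1734 and 1059 in cmt, 1698 and 176 in dnmt3b, 2930 genes in met/dnmt3b, 3978 and 3621 features in met/dnmt3b with met and with dnmt3b, and 2140 and 2526 in the interactions.

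In batch 1 alone 1321 TEs passed the filter instead of 6602, and there were 1081 genes in met, 238 TEs in cmt and 809 TEs in met/dnmt3b. In batch 2 alone, where a single wt library is assumed to vary like the other groups and 7792 TEs passed, there were 1763 and 105 in drm12, 621 and 378 in cmt, 539 and 53 in dnmt3b and 614 in the interaction of cmt with dnmt3b. Without the drm12 libraries there were 2181 and 259 in met, 1667 genes in cmt, 474 and 57 in dnmt3b, 4524 genes in met/dnmt3b, 4392 in met/dnmt3b with met, 3793 in cmt/dnmt3b with met/dnmt3b, and 1329 and 3476 in the interactions.

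With factors from genes alone and the 7 chromosomes left out, there were 2648 genes in cmt/dnmt3b and 923 features in the interaction of cmt with dnmt3b. An absolute log2 fold change of at least 1 left 3002 genes in cmt/dnmt3b. Adjusting genes and TEs separately gave 61 and 183 in met, 16 TEs in dnmt3b and 1011 genes in met/dnmt3b. Without the TE with the most counts, the TE share of met exceeded that of wt by 0.0909 points instead of 0.122.

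With 1 library left out in turn, the counts of genes ran from 1 to 18 in drm12, 13 to 196 in met, 596 to 1255 in cmt, 44 to 249 in dnmt3b, 987 to 1821 in met/dnmt3b and 1676 to 4223 in cmt/dnmt3b. Those of TEs ran from 2 to 8, 35 to 268, 285 to 595, 9 to 24, 1980 to 3208 and 803 to 5217. Features ran from 148 to 2127 in met/dnmt3b with met, 1476 to 1853 with dnmt3b, 2946 to 5715 in cmt/dnmt3b with cmt, 8769 to 11135 with dnmt3b, 889 to 1384 with met/dnmt3b, 125 to 1100 in the interaction of met with dnmt3b and 550 to 1701 in that of cmt with dnmt3b. The libraries that moved a count by over 1.5 times are named with the comparisons.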

Other observations

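The tests on whole chromosomes, on batch 2 and on reads from other libraries or genomic DNA were chosen after the results were seen; so was the present test of a wrong label. Those on genes of low and high level and on neighbouring genes were written before their results were seen.

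In the 3 cmt/dnmt3b libraries, genes of chromosome 16 stood 0.84 ± 0.03 above their median over the 20 libraries and those of chromosome 10 stood 0.55 ± 0.07 above theirs (log2). Batch 2 is argued against (highest chromosome 16 median of its other libraries -0.033), as is an extra copy of a part of chromosome 10 that spares a whole one of its 4 parts (the lowest in any of the 3 libraries 0.40, the highest in the other libraries 0.08; this replaced a bound of 0.4 on the mean of the 3, 0.48). An extra copy of chromosome 16 may account for its shift, with a median of 0.76 in the lowest of its 4 parts, and stays open. A copy of the whole of chromosome 10, which lay 0.29 ± 0.07 below chromosome 16, stays open too. A simulated doubling of the transcripts of 1 chromosome in these 3 libraries gave 0.80 to 0.84 by the same measure. Chromosome 16 lay at 0.82 to 0.87 and chromosome 10 at 0.46 to 0.59. No DNA was measured, and how far a real copy raises transcripts is not known. The 230 genes of chromosome 16 with the lowest level had a median 0.36 above that of its 230 with the highest. That is past the bound of 0.3 written beforehand, which alone would count against a copy acting alike on all genes. The bootstrap interval (0.28 to 0.44, including 0.3) and the 0.18 to 0.27 of 20 other chromosomes were added after that value was seen. So that test is left undecided. Whether the genotype or a culture's history carries the shift cannot be told apart, because all cmt/dnmt3b libraries share it.

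In wt replicate 3, genes of chromosome 19 stood 0.91 above their median over the 20 libraries (log2), with a median of 0.89 in the lowest of its 4 parts, so an extra copy of that chromosome in that culture is a candidate explanation. Batch 2 is argued against, since the highest chromosome 19 median of its other libraries was 0.042. No biological explanation that the design names was tested, because the other wt libraries do not share it.

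The TE share of drm12 replicate 3 (0.270%) lay above those of drm12 replicates 1 and 2 (0.0874% and 0.0809%). Reads from the cmt/dnmt3b libraries would need 5.79% of the cmt/dnmt3b level, and the median over its 100 top TEs was 0.490%, which argues against them, although the summed share of these TEs was 4.67% because a few TEs carry it. A dnmt3b library under the wrong label is argued against: of 310 features called between dnmt3b and wt, drm12 replicate 3 was nearer to dnmt3b at 7.74%. The value was 17.4% and 12.3% in drm12 replicates 1 and 2 and 2.58 to 13.2% in the wt libraries. It was 98.4 to 99.7% in the dnmt3b libraries, which is high by selection, since they defined these features. This test replaced 2 earlier versions with few features, the last at 42.9% of 7. Genomic DNA stays open: a first measure, 39.1% of TE counts in rows with at least 50 counts, did not exclude it, a second, chosen after the first was seen, 23.8% of TE counts in rows under 10 counts against the 68.8% added, counts against it, and an even spread over TEs is itself assumed. Loss of DRM1 and DRM2 stays open but untested for a rise in 1 of 3 libraries.

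A hypothesis was that genes that rose lie next to each other more often than by chance. On 20 chromosomes with 15905 tested genes, neighbouring pairs that both rose numbered 95 in met/dnmt3b against a permuted mean of 45.5 (ratio 2.09), 169 in cmt/dnmt3b against 79.7 (ratio 2.12) and 53 in cmt against 15.6 (ratio 3.40). Each had a permutation p of 0.0001, the smallest that 10000 permutations can give. Split gene models or transcripts that run from a gene into the next could also give such pairs and were not tested.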
